A study of Mus musculus with 54 samples.

How the data were processed

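RNA was measured in mouse embryonic stem (ES) cells derived from 3 inbred strains and cultured at 31 °C or at 37 °C. The labels name the strains B6J (C57BL/6J in the sample titles), STM2 and MYS. There were 9 cell lines, 3 per strain, named B6J#02, B6J#03 and B6J#06, STM2#01, STM2#02 and STM2#03, and MYS#02, MYS#04 and MYS#05. Each line had 3 biological replicates at each temperature, which gave 54 libraries in 18 groups. The series text speaks of 3 ES cell lines, and each of the 9 line labels was taken as a separate line. If lines of a strain are not independent, the p-values are too small. The labels name a column-based kit for total RNA and a stranded library kit that selects polyadenylated RNA. The medium, the feeder cells, the time spent at 31 °C, the sex of the lines and the days of culture are not given in the sources used here.

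The deposited values are raw read counts per gene and library, which the authors obtained by aligning reads to the mouse genome build GRCm38 with HISAT2 2.1.1 and counting them with featureCounts 2.0.0. The annotation release and the strand setting of the counting are not given in the sources used here. Of the 55471 genes listed, 55144 had a symbol and a position in GENCODE vM21. Genes without a symbol held 0.029% of the counts. Library totals ranged from 15.8 to 25.8 M counts (M, 1e+06), with a median of 19.4 M. At such totals a gene with 0 counts over a group could still be present at up to 3 counts over that group, which was used as the floor of every lower bound on a fold. Ratios that rest on 1 to 3 counts are given with a 95% binomial counting interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

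The cell line was taken as the unit of replication. Counts of the 3 replicates of a line at 1 temperature were summed, which gave 18 summed libraries. Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15) and libraries were scaled by the trimmed mean of M values (TMM). The quasi-likelihood F test of edgeR (glmQLFit and glmQLFTest) was fitted with the cell line as a block and with one 31 °C term per strain. From this fit came the common response, which is the mean of the 3 strains' log2 fold changes at 31 °C over 37 °C, the response of each strain, the test that the 3 responses are equal, and the pairwise differences between responses. Strains at 37 °C were compared on the 9 summed libraries at that temperature, with their own filter and scaling. The response of each line was tested on its own 6 libraries. All these tests are two-sided. The p-values were adjusted by the method of Benjamini and Hochberg over the genes tested, with a threshold of 0.05. Expression is given in CPM (counts per 1e+06 counts) on TMM-scaled library sizes, as mean ± SD over the 3 lines of a strain. Exceptions are the summed levels of the 2-cell-like list and the CPM of Xist and of summed Y-linked genes in single libraries. These are on library totals without scaling factors. SE is the standard error of a log2 fold change. Fold changes per line used a prior count of 2.

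There were 39 gene lists, written down before the data were examined, as were the comparisons, the tests and the rule for naming genes. Lists were tested with camera of limma 3.58.1 on voom log2 CPM with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation and the test fry were run as alternatives. For each list the members past the threshold over all genes tested were counted, as were the members that passed when adjusted over the list alone. Principal components were computed on the 1000 most variable genes.

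Genes were named by rule. For the common response these are the 10 genes with the highest and the 10 with the lowest log2 fold change among those past the threshold, with a mean of at least 5 CPM and the same direction in 9 of 9 lines. For each difference between a pair of strains they are the 5 highest and the 5 lowest among genes past the threshold, with a mean of at least 5 CPM and no overlap between the lines of the strains. In each list they are the 2 highest and the 2 lowest members in the common response, and up to 4 members with the smallest p in any other comparison in which the list passed. Cirbp, Rbm3, Pou5f1, Sox2, Nanog, Xist and Ddx3y are always reported. Of the 10 lowest genes, 2 are not reported here. Unnamed gene models were counted but not named under the first parts of the rule. The 327 genes so picked were searched for near-identical copies among annotated transcripts with BLAST 2.17.0 (identity of at least 95% over at least 50% of the transcript), and 47 had at least 1. Genes with several copies share reads or lose them, so their counts were read with that limit.

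The fit was tested on simulated data in which 200 genes were changed. For the common response it recovered 57.8% of genes changed 1.25-fold and 89.8% of genes changed 2-fold, with calls in 0.033% of unchanged genes. A difference of 2-fold between a pair of strains was recovered in 58.3% of genes for the responses and in 60.9% at 37 °C. In one line alone 84% of genes changed 2-fold were recovered. Simulated changes went in both directions alike, and the spread of each gene followed the trend with abundance. In the data 14550 of 23055 genes passed for the common response, so these rates need not hold there.

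Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, every library as a sample, a fit without the cell line block, a block for the replicate number, autosomal genes only, and leaving out each library and each line. Added after the data were seen were library sizes without scaling factors, protein-coding genes only, and a fit without both lines that nearly lacked Y-linked reads. Each comparison was repeated on other splits of the samples, with at most 40 drawn splits. Replicates were compared in pairs by a chi-square per degree of freedom, and no library was excluded. R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used. A table of all libraries held the same counts as the tables of single libraries and was not used here.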

Results

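The 9 mouse ES cell lines separated first by strain and then by temperature. The first component of variation among the 54 libraries held 59% of the variance of the 1000 most variable genes and the second held 32.1%, and both set the strains apart. The third component held 2.5% and set 31 °C apart from 37 °C. Reads from the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to between 168 and 384 CPM in the libraries of 7 lines. B6J#06 had 16 such counts and MYS#04 had 3 over their 6 libraries each. Xist, the RNA that coats the inactive X chromosome, stayed at or under 2.69 CPM in every library.

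**Figure D1:**
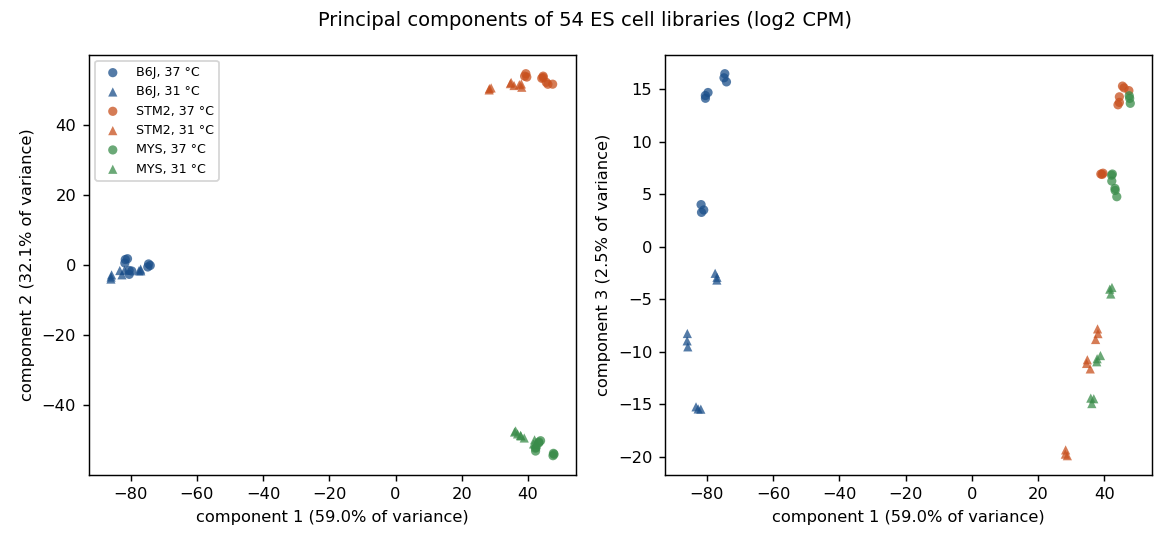
Each point is 1 of the 54 libraries, placed by its principal components of log2 CPM, with the share of variance on each axis and strain and temperature shown by colour and shape. Strains separate on components 1 and 2 (59% and 32.1% of the variance), and temperatures on component 3 (2.5%).

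The common response asks what ES cells of all 3 strains do at 31 °C. The RNA-binding protein genes Cirbp and Rbm3, known for their induction by mild cold, rose in every line. The strongest rise among well-expressed genes was that of Taf7l, a germ-cell paralog of a subunit of the general transcription machinery. Nkx1-2, a homeobox gene of the posterior epiblast, and Ephx2, which encodes soluble epoxide hydrolase, fell most. By a test with a preset correlation between genes, lists for ribosomal proteins, DNA replication, respiratory complexes and glycolysis fell and p53 targets rose. With an estimated correlation 0 of 39 lists passed. Histone genes and genes of the 2-cell-like state rose in the mean of the strains, but the former did not pass in STM2 (camera adjusted p = 0.888) nor the latter in MYS (0.901).

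Of 23055 genes tested, 14550 passed the threshold, 7527 higher and 7023 lower at 31 °C. A change of at least 2-fold was found in 2649 genes that rose and in 683 that fell. Cirbp (ENSMUSG00000045193, chromosome 10, 80165985 to 80172786 in GRCm38) had a log2 fold change of 1.64 (SE 0.04, edgeR adjusted p = 9.1e-13). Its mean level went from 54.4 to 172 CPM in B6J, from 68.0 to 224 in STM2 and from 89.7 to 262 in MYS, each over 3 lines. Rbm3 (ENSMUSG00000031167, chromosome X, 8138975 to 8145880) rose by 0.93 (SE 0.03, adjusted p = 6.4e-11), from 258 to 467 CPM in B6J, from 133 to 254 in STM2 and from 122 to 243 in MYS. The responses of Cirbp and Rbm3 were not found to differ among strains (adjusted p = 0.29 and 0.49).

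Taf7l (ENSMUSG00000009596, chromosome X, 134460118 to 134476490) had a log2 fold change of 4.25 (SE 0.10, adjusted p = 1.8e-12) and went from 1.45 to 59.2 CPM in STM2. The xenobiotic-metabolising cytochrome genes Cyp1b1 (3.18, SE 0.24) and Cyp1a1 (2.23, SE 0.21), both targets of the aryl hydrocarbon receptor, rose as well. So did the neural transcription factor gene Sox21 (2.44) and the growth arrest gene Gadd45g (2.32). Ptges (2.14), which encodes a prostaglandin E synthase, and Slco2a1 (2.31), which encodes a prostaglandin transporter, rose together. Fbln5 (2.22), Fndc10 (2.17) and the germline gene Dmrtb1 (2.1) complete the 10 highest, whose adjusted p-values ran from 1.8e-12 to 3e-07. Nkx1-2 (ENSMUSG00000048528, chromosome 7, 132594878 to 132599637) changed by −4.28 (SE 0.11, adjusted p = 5.2e-12), from 23.7 to 1.21 CPM in B6J. Ephx2 changed by −3.90 (SE 0.14), from 112 to 14.8 CPM in B6J, from 53.4 to 1.69 in STM2 and from 68.7 to 6.20 in MYS. The bicarbonate transporter gene Slc4a5 (−2.75), Pou2f3 (−2.62) and the thyrotropin-releasing hormone gene Trh (−2.53) followed. Epp13 (−2.27), Slfn9 (−2.21) and Ap3b2 (−2.11) were lower too, and adjusted p-values of these 8 genes ran from 5.2e-12 to 9.8e-10. Each of these 18 genes moved in the same direction in 9 of 9 lines, as the naming rule requires.

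**Figure D2:**
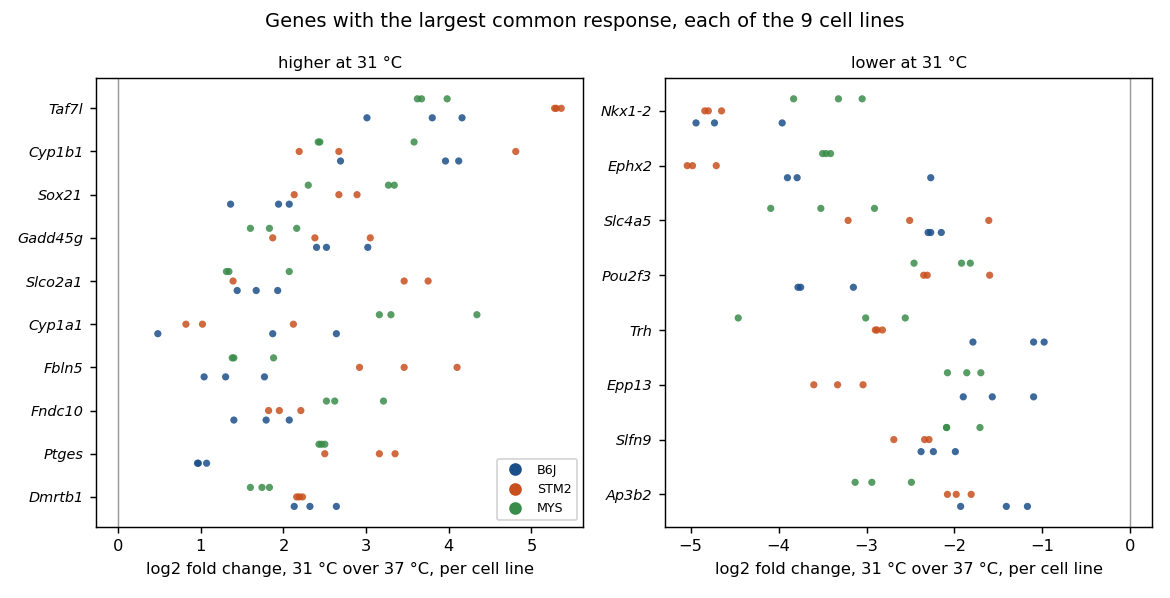
Each dot is the log2 fold change (31 °C over 37 °C) of 1 of the 9 cell lines, coloured by strain, for the 10 highest genes of the common response and 8 of the 10 lowest. All dots of a gene lie on the same side of 0, as the naming rule requires, with Taf7l at a common value of 4.25 and Nkx1-2 at −4.28.

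Low-abundance genes rose and abundant genes fell. Genes under 1 CPM on average had a median log2 fold change of 0.38, with 2762 higher and 672 lower among 8100. The median was 0.12 among 5171 genes from 1 to 10 CPM, −0.08 among 7346 genes from 10 to 100 CPM, and −0.15 among 2438 genes at 100 CPM or more, of which 452 rose and 1524 fell. The split into higher and lower therefore depends on the scaling. On library sizes without scaling factors, chosen after the data were seen, the median of all genes moved from 0.03 to 0.18, and 10319 genes were higher and 4438 lower. Changes are given relative to the TMM scaling, and 7 of the 39 list medians change sign without it. These are the cold-inducible genes, general pluripotency, feeder fibroblast genes, mitochondrially encoded subunits, targets of the hypoxia factor HIF, the proteasome and the lysosome.

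Genes for growth and energy metabolism fell at 31 °C with the preset correlation, and 0 of 39 lists passed with an estimated one. Part of each fall rests on the scaling. Without scaling factors the median moves from −0.25 to −0.09 for cytosolic ribosomal proteins, from −0.21 to −0.05 for complexes I and II and from −0.23 to −0.07 for G2/M and mitosis. Abundant genes fell in general, as given above. In this and the next paragraphs on lists, members adjusted over the list alone gave the same counts unless others are given, and named members moved the same way in 9 of 9 lines unless stated. In the list of 96 cytosolic ribosomal protein genes 5 rose, 81 fell and 10 did not pass (camera adjusted p = 2.84e-18, adjusted p = 0.286 with an estimated correlation; 83 fell when adjusted over the list alone). The list matched symbols only and holds 10 S6 kinase genes (3 higher, 5 lower) and 7 paralogs with a name ending in l or l1 (2 higher, 4 lower). Of the other 79, which include the binding protein gene Rps19bp1, 72 fell and 0 rose. Rpl39l (−1.69), 1 of the paralogs, and Rpl13a (−1.09) fell most. All 24 genes of DNA replication and the G1/S transition fell (2.02e-10, adjusted p = 0.426 with an estimated correlation), with Pola1 (−1.07) and Uhrf1 (−0.80) lowest. Of 22 genes of G2/M and mitosis 21 fell (3.72e-07, adjusted p = 0.461 with an estimated correlation), among them Top2a (−0.60) and Ube2c (−0.52). Ribosome biogenesis had 1 gene higher and 18 lower of 26 (2.32e-06, adjusted p = 0.474 with an estimated correlation; 20 lower adjusted over the list alone), with Npm1 (−0.70) and Bop1 (−0.65) lowest. Nuclear genes of respiratory complexes III to V fell in 34 of 37 cases and rose in 0 (4.76e-11, adjusted p = 0.426 with an estimated correlation), including Atp5e (−0.56) and Atp5d (−0.53). Complexes I and II had 32 lower and 1 higher of 41 (3.72e-07, adjusted p = 0.461 with an estimated correlation), with Ndufb2 (−0.85) and Ndufa13 (−0.70) lowest. The tricarboxylic acid cycle had 17 lower and 0 higher of 19 (7.95e-07, adjusted p = 0.286 with an estimated correlation; 18 lower adjusted over the list alone), with Ogdh (−0.83) and Idh2 (−0.55) lowest. Glycolysis had 17 lower and 2 higher of 20 (7.95e-07, adjusted p = 0.286 with an estimated correlation). Pfkl (−1.73), a phosphofructokinase, and Slc16a3 (−1.31), a lactate exporter, fell, and the glucose transporter genes Slc2a1 (0.16, 9 of 9 lines) and Slc2a3 (0.27, 7 of 9 lines) rose. The 13 mitochondrially encoded subunits did not shift as a list (adjusted p = 0.690), with 5 higher and 4 lower, mt-Nd1 (0.44) highest. The share of all counts from mitochondrial DNA, not scaled, was higher at 31 °C in 9 of 9 lines, at 1.53 to 2.21% against 1.21 to 1.74%.

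Stress genes moved apart. Chaperone genes fell, with 20 lower and 8 higher of 29 (0.000357, adjusted p = 0.426 with an estimated correlation). The heat shock gene Hsph1 (−1.45) and the collagen chaperone gene Serpinh1 (−1.36) fell, whereas Cryab (1.52) and Dnajb4 (1.30) rose. The unfolded protein response of the endoplasmic reticulum had 11 lower and 2 higher of 18 (0.0117, adjusted p = 0.633 with an estimated correlation), with Hsp90b1 (−0.79) and Herpud1 (−0.76) lower and Dnajc3 (0.41) higher. It did not pass in STM2 (0.142). Targets of ATF4, the transcription factor of the integrated stress response, had 16 lower and 1 higher of 22 (6.70e-05, adjusted p = 0.50 with an estimated correlation). This rests on STM2 (18 lower, 0 higher) and MYS (19 lower, 0 higher; 20 lower adjusted over the list alone), while B6J had 6 higher and 7 lower and did not pass (0.48). Nupr1 (−1.48) and Chac1 (−1.43) fell most, and Cebpb (0.50) rose in 8 of 9 lines. Targets of p53 rose, 16 higher and 3 lower of 20 (0.00200, adjusted p = 0.50 with an estimated correlation), with Perp (1.52) highest and Plk2 (0.85) higher in 8 of 9 lines. The proteasome had 17 lower and 5 higher of 31 (0.0391, adjusted p = 0.661 with an estimated correlation), with Psmd7 (−0.39) lowest, and its median flips from −0.09 to 0.07 without scaling factors. It passed in no single strain (0.0792 to 0.150). Lists that did not pass were NRF2 targets (9 higher, 10 lower of 22, 0.664), HIF targets (6 higher, 8 lower of 20, 0.276), apoptosis regulators (10 higher, 5 lower of 20, 0.276) and lysosome and autophagy (8 higher, 14 lower of 28, 0.276). Within them Nqo1 (1.02), Bcl2 (1.66), Bok (1.23) and Wipi1 (0.79) rose, and Fam162a (−1.22), Cycs (−0.74) and Hexa (−0.93) fell. Cold-shock-domain proteins had 1 higher and 4 lower of 7 (0.174), where Lin28a (−1.23), a repressor of let-7 microRNAs, fell most. The cold-inducible list, Cirbp and Rbm3 included, had 4 higher and 6 lower of 12 (0.519), with Rbm10 (−0.52) and Tra2a (−0.50) lowest.

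Naive and general pluripotency genes fell as lists in B6J alone with the preset correlation, and in no strain with an estimated one. The test fry called both lower in B6J (adjusted p = 0.00182 and 0.00226) and in the mean of the strains (0.00284 and 0.003025). Pou5f1 changed by −0.39 (SE 0.04, adjusted p = 7.1e-07) and Sox2 by −0.30 (SE 0.03, 1.9e-06), but Nanog by 0.03 (SE 0.03, 0.45), which becomes a rise of 0.19 (3.8e-05) without scaling factors. With the preset correlation, neither naive pluripotency (5 higher, 10 lower of 19, 11 lower adjusted over the list alone, 0.125), general pluripotency (4 higher, 7 lower of 15, 0.183) nor formative pluripotency (4 higher, 8 lower of 16, 5 higher adjusted over the list alone, 0.287) passed in the mean of the strains. In B6J naive pluripotency had 13 lower and 1 higher (0.000132, adjusted p = 0.433 with an estimated correlation) and general pluripotency 10 lower and 1 higher (0.0117, adjusted p = 0.439 with an estimated correlation). Neither passed in STM2 (0.506 and 0.888) or MYS (0.901 and 0.347). Tcl1 (−1.43), L1td1 (−0.77), Grhl2 (−1.28) and Lef1 (−1.15) fell, and Klf4 (0.36, 6 of 9 lines) and Dppa3 (0.54, 7 of 9 lines) rose. Among lineage lists only primitive and definitive endoderm passed in the mean of the strains, with 10 higher and 2 lower of 18 (0.0383, adjusted p = 0.286 with an estimated correlation; 3 lower adjusted over the list alone), led by Dab2 (1.91) and Foxq1 (1.68). Within strains it passed in MYS (0.0307, adjusted p = 0.286 with an estimated correlation) and not in B6J (0.0747) or STM2 (0.0897). Trophectoderm had 7 higher and 3 lower of 15 (8 higher adjusted over the list alone, 0.132), with Hand1 (2.28) and Krt7 (1.47) highest. In STM2 alone it passed, with 9 higher and 2 lower (0.0226, adjusted p = 0.292 with an estimated correlation). Primitive streak and mesoderm had 4 higher and 8 lower of 19 (5 higher adjusted over the list alone, 0.265), with Lefty2 (−1.97) and T (−1.72) lower and Kdr (1.51) higher. Neuroectoderm had 7 higher and 3 lower of 13 (4 lower adjusted over the list alone, 0.690), with Pax6 (1.61) higher and Ncam1 (−1.06) lower. Feeder fibroblast genes had 6 higher and 4 lower of 14 (0.519), with Loxl1 (2.35) and Col6a2 (1.67) highest. Germline genes had 10 higher and 5 lower of 16 (0.174), with Stra8 (1.66, 8 of 9 lines) beside Taf7l, and Rhox5 (−1.50) and Dnmt3l (−1.26) lowest. Imprinted genes had 7 higher and 12 lower of 24 (13 lower adjusted over the list alone, 0.324), with Nnat (1.58) highest and Peg10 (−1.18) and Igf2r (−1.16) lowest.

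Genes of the 2-cell-like state, a rare state of ES cells marked by the Zscan4 cluster, had 14 higher and 0 lower of 20 (0.0337, adjusted p = 0.633 with an estimated correlation) and did not pass in MYS (0.901). Their summed level, not scaled, rose in 8 of 9 lines. In B6J it went from 229 to 400 CPM in B6J#02, from 76.7 to 148 in B6J#03 and from 131 to 449 in B6J#06. It was lower by orders of magnitude in STM2, where it rose from 0.20 to 2.11 CPM in STM2#01, from 0.69 to 6.85 in STM2#02 and from 0.28 to 1.24 in STM2#03. RNA from B6J cells making up 0.287 to 1.84% of these libraries would give such a rise, and it was not excluded. In MYS it rose from 2.81 to 5.18 CPM in MYS#02 and from 0.99 to 1.79 in MYS#04, and fell from 13.3 to 10.3 in MYS#05. Zscan4 genes have 8 near-identical annotated copies each, so counts of single members are less certain than the sum. Genes of replication-dependent histones rose in 23 of 48 cases and fell in 0 (0.0101, adjusted p = 0.286 with an estimated correlation; 22 higher adjusted over the list alone), with Hist1h1c (1.84) and Hist3h2ba (1.67) highest. In STM2 the list did not pass (0.888). Their transcripts mostly lack poly(A) tails, so the reads come from the part that this library type captured.

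**Figure D3:**
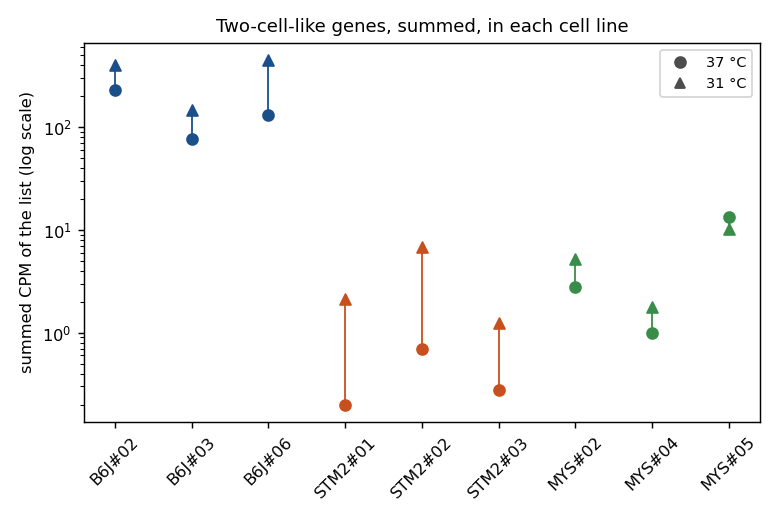
Summed CPM (log scale) of the 20 genes of the 2-cell-like list, on library totals without scaling factors, in each of the 9 cell lines. Circles are at 37 °C and triangles at 31 °C, each the sum over 3 replicates. B6J lines lie between 76.7 and 449 CPM and STM2 lines between 0.20 and 6.85 CPM, and the sum is higher at 31 °C in 8 of 9 lines.

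Lipid genes fell in part. Cholesterol synthesis had 16 lower and 1 higher of 25 (0.00683, adjusted p = 0.633 with an estimated correlation), with Tm7sf2 (−0.88) and Dhcr7 (−0.76) lowest and Hsd17b7 (0.39) higher. Fatty acid synthesis and desaturation had 10 lower and 5 higher of 19 (0.132), where the desaturase genes Scd2 (−1.41) and Scd1 (−1.06, 8 of 9 lines) fell and Mlxipl (1.59) and Fads3 (1.56) rose. In MYS alone it passed, with 12 lower and 5 higher (0.0213, adjusted p = 0.584 with an estimated correlation). Uncoupling and mitochondrial biogenesis had 10 lower and 2 higher of 14 (0.0144, adjusted p = 0.286 with an estimated correlation) and did not pass in B6J (0.0737). Ppargc1b (−0.56) and Slc25a5 (−0.54) fell, and Cidea (1.57), a lipid droplet gene of brown fat, rose. Among clock genes Per2 (1.58) and Bhlhe41 (1.18) rose and Bhlhe40 (−1.08) fell, with 9 higher and 4 lower of 17 (0.179). Tubulins and microtubule regulators had 4 higher and 11 lower of 18 (0.0899), with Stmn1 (−0.53) lowest. Immediate early genes had 7 higher and 5 lower of 16 (8 higher adjusted over the list alone, 0.664), with Fos (1.08) higher and the growth factor feedback gene Spry4 (−1.33) lower. The list of 5 Y-linked genes did not pass (0.512), and its values average over 2 lines that nearly lack their reads, so its members are not read further. Ddx3y (−0.03, SE 0.04, adjusted p = 0.52) has the same limit and turns to 0.12 (0.015) without scaling factors. Xist (0.06, SE 0.16, 0.79) did not pass. In all, 18 of the 39 lists passed, 4 higher and 14 lower, and 0 passed with an estimated correlation. The test fry, which asks whether a list moves on balance without reference to other genes, called 32.

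**Figure D4:**
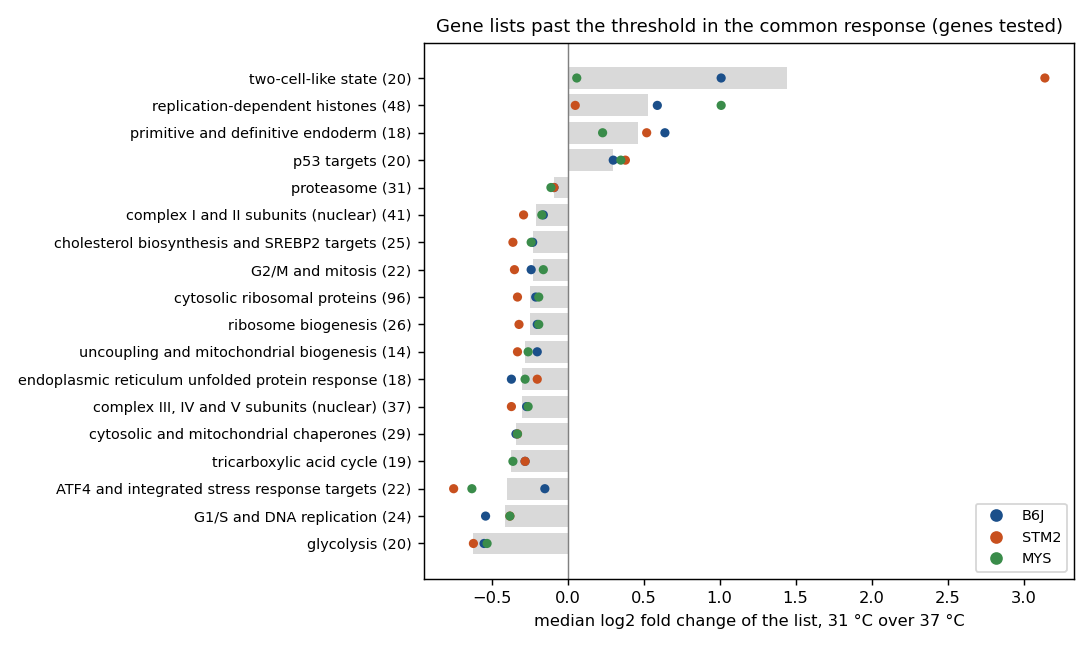
Bars give the median log2 fold change (31 °C over 37 °C) of the common response for the 18 gene lists past the threshold, with the number of genes tested in brackets, and dots give the medians of the 3 strains. Without scaling factors the proteasome flips to 0.07, and in B6J alone the ATF4 targets and complexes I and II flip to 0.01.

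The response was broad within each strain. In B6J 10870 genes passed, 5273 higher and 5597 lower, with 2286 higher and 868 lower by at least 2-fold. In STM2 11839 passed, 5845 higher and 5994 lower, with 2635 and 1056 by at least 2-fold. In MYS 10676 passed, 5331 higher and 5345 lower, with 2317 and 806 by at least 2-fold. Without scaling factors the splits were 7682 higher and 3371 lower in B6J, 7992 and 3827 in STM2, and 7409 and 3438 in MYS. Within single lines, over 3 replicates at each temperature, 11090 genes passed in B6J#02, 10225 in B6J#03 and 10615 in B6J#06. There were 10905 in MYS#02, 9907 in MYS#04 and 9942 in MYS#05, and 11218 in STM2#01, 11318 in STM2#02 and 8843 in STM2#03. Replicate 1 of STM2#03 at 37 °C lay apart from the other replicates, with a chi-square per degree of freedom of 26.5 and 19.9 against 2.45 between those, and without it the count was 10403.

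Strains differed in the size of the response for 6288 of 23055 genes, among them Pou5f1, Nanog and Lin28a. The count was 3211 without the 2 lines that nearly lack Y-linked reads, 536 without the cell line block and 12909 with every library a sample. Pou5f1 changed by −0.66 in B6J, −0.32 in STM2 and −0.19 in MYS (adjusted p for a difference among strains = 0.0067), where it did not pass without any 1 of the 3 MYS lines (0.079 to 0.14). Nanog changed by −0.20 in B6J, 0.17 in STM2 and 0.12 in MYS (0.0039), with no call in MYS and none in STM2 without STM2#01 (0.10). Without scaling factors Nanog no longer passed in B6J but did in MYS (0.26), and Pou5f1 no longer passed in MYS. Among protein-coding genes alone Nanog passed in MYS (adjusted p = 0.041) and Pou5f1 did not (0.053). Lin28a changed by −2.29 in B6J, −0.86 in STM2 and −0.53 in MYS (0.0021), the last not past without MYS#02, MYS#04, MYS#05, B6J#02, STM2#01 or replicate 3 of STM2#01 at 37 °C (0.051 to 0.18). Nor did it pass with DESeq2 (0.17), without scaling factors (0.13), among protein-coding genes alone (0.063) or without the cell line block (0.60).

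Single genes moved in opposite directions in STM2 and B6J. The activin subunit gene Inhbb, the acetylcholine receptor gene Chrna4 and the oligodendrocyte factor gene Olig2 rose in STM2 and fell in B6J. The adhesion receptor gene Adgrd1 did the reverse. ATF4 targets, among them the serine synthesis genes Phgdh, Psat1 and Psph, fell in STM2 but did not pass as a list in B6J, and pluripotency genes were relatively higher in STM2. These list differences did not pass with an estimated correlation (adjusted p = 0.518 to 0.599).

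The response of STM2 was higher than that of B6J for 2380 genes and lower for 1772. Olig2 changed by 1.63 in STM2 and −1.58 in B6J, a difference of 3.20 (SE 0.41, adjusted p = 0.00018; the rise in STM2 did not pass without STM2#03, 0.072), from 0.271 CPM at 37 °C in STM2 against 68.9 in B6J. Inhbb changed by 2.14 and −0.88, a difference of 3.02 (SE 0.29, 2.8e-05). Chrna4 changed by 1.82 and −1.03, a difference of 2.86 (SE 0.20, 4.4e-06). The butyrophilin gene Btn1a1 rose by 3.03 in STM2, from 4.68 to 35.8 CPM, and did not pass in B6J (log2 0.34), a difference of 2.69. The lectin receptor gene Clec4a1 fell in B6J (−2.22) and did not pass in STM2 (log2 0.35), a difference of 2.57. It did pass there without STM2#02 (adjusted p = 0.0036), without scaling factors (0.024) and without a filter (0.0098). Adgrd1 changed by −2.32 in STM2 and 0.78 in B6J, a difference of −3.10 (SE 0.17, 1.1e-06). Exoc3l2 (difference −2.52), Dmgdh (−2.03) and Ptgs1 (−2.03) fell in STM2 and did not pass in B6J. Wnt8a rose by 2.33 in B6J, from 0.283 to 1.41 CPM, and did not pass in STM2, a difference of −2.19 (SE 0.60, 0.021), lost without B6J#02, B6J#03, STM2#01 or STM2#03 (adjusted p up to 0.10). For each of these genes the lines of both strains did not overlap, as the naming rule requires. ATF4 targets were lower in 17 of 22 cases and higher in 0 (18 lower adjusted over the list alone, 1.31e-11, adjusted p = 0.518 with an estimated correlation, median −0.81). Among them were Psph (−0.95), Phgdh (−0.85), Psat1 (−0.78) and Nupr1 (−1.85). Naive pluripotency had 8 higher and 0 lower of 19 (9 and 1 adjusted over the list alone, 0.00258, adjusted p = 0.599 with an estimated correlation), including Klf4 (0.66), Sox15 (0.82), Tet2 (0.80) and Nanog (0.38). General pluripotency had 7 higher and 0 lower of 15 (8 higher adjusted over the list alone, 0.00247, adjusted p = 0.518 with an estimated correlation), including Dppa4 (0.67) and Gdf3 (0.48). DNA replication and G1/S had 7 higher and 0 lower of 24 (0.000225, adjusted p = 0.599 with an estimated correlation), including Pola1 (0.64) and Mcm4 (0.36). The unfolded protein response had 3 higher and 1 lower of 18 (4 higher adjusted over the list alone, 0.00416, adjusted p = 0.599 with an estimated correlation), including Pdia4 (0.45). Ribosomal protein genes were lower in STM2, 21 against 1 higher of 96 (34 and 2 adjusted over the list alone, 1.31e-11, adjusted p = 0.518 with an estimated correlation), among them Rps19 (−0.37). Complexes I and II had 8 lower and 1 higher of 41 (5.14e-05, adjusted p = 0.599 with an estimated correlation) and complexes III to V 6 lower and 0 higher of 37 (0.000225, again 0.599), including Ndufb9 (−0.36) and Cox5b (−0.37). Ribosome biogenesis had 3 lower and 1 higher of 26 (2 lower adjusted over the list alone, 0.00486, adjusted p = 0.662 with an estimated correlation), with Rrp12 (−0.38). Histone genes had 3 lower and 0 higher of 48 (1 lower adjusted over the list alone, 0.00287, adjusted p = 0.518 with an estimated correlation), with Hist1h3e (−1.28). The count of 4152 genes fell to 2753 without STM2#01.

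Between MYS and B6J single genes also moved in opposite directions. Irak3, a brake on interleukin and Toll-like receptor signalling, and the haematopoietic gene Nckap1l rose in MYS and fell in B6J. The stress factor gene Atf3 and the signalling gene Wnt8a rose in B6J and fell in MYS, but the fall of Atf3 was lost without scaling factors (0.064) and that of Wnt8a with DESeq2 (0.059). Naive pluripotency genes such as Klf4 and Prdm14 were relatively higher in MYS, a list result lost with an estimated correlation (0.848).

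The response of MYS was higher than that of B6J for 1909 genes and lower for 1431. Clec4a1 changed by 1.53 in MYS and −2.22 in B6J, a difference of 3.75 (SE 0.55, adjusted p = 0.00065). Nckap1l changed by 2.24 and −0.97, a difference of 3.21 (SE 0.36, 0.00011), from 0.137 CPM at 37 °C in MYS against 25.8 in B6J. Cttnbp2 (1.84 and −0.99), Irak3 (0.98 and −1.84) and Slco4c1 (1.30 and −1.40) also moved in opposite directions, with differences of 2.83, 2.82 and 2.71. Wnt8a changed by −1.19 in MYS and 2.33 in B6J, a difference of −3.52 (SE 0.62, 0.002). Hs6st2, a heparan sulfate modifying gene, changed by −1.89 and 1.13, a difference of −3.02 (SE 0.41, 0.00039). Atf3 changed by −0.69 and 1.53, a difference of −2.22 (SE 0.31, 0.00043). Trh fell in both strains, by 3.42 in MYS and by 1.29 in B6J, with a difference of −2.13. Nt5e fell in MYS (−2.07) and did not pass in B6J, with a difference of −2.05. Naive pluripotency had 12 higher and 0 lower of 19 (13 and 1 adjusted over the list alone, 0.000181, adjusted p = 0.848 with an estimated correlation), including Klf4 (0.75), Tet2 (1.00), Tfcp2l1 (0.51) and Prdm14 (1.01). General pluripotency had 6 higher and 2 lower of 15 (9 higher adjusted over the list alone, 0.0209, adjusted p = 0.848 with an estimated correlation), with L1td1 (0.99) higher and Fbxo15 (−0.82) lower. DNA replication and G1/S had 6 higher and 1 lower of 24 (7 higher adjusted over the list alone, 0.00176, adjusted p = 0.992 with an estimated correlation), with Uhrf1 (0.55) higher. ATF4 targets had 12 lower and 0 higher of 22 (13 and 1 adjusted over the list alone, 1.20e-07, adjusted p = 0.848 with an estimated correlation). Slc7a11 (−2.28), the cystine importer, Chac1 (−1.43) and Vldlr (−1.18) were lower there. NRF2 targets had 7 lower and 2 higher of 22 (8 lower adjusted over the list alone, 0.00950, adjusted p = 0.848 with an estimated correlation), with Txnrd1 (−0.79), Nqo1 (−0.66) and Gclc (−0.64) lower. Within single strains, Clec4a1, Irak3, Wnt8a and Atf3 did not pass in MYS without MYS#04 (0.073 to 0.21), and Hs6st2 did not pass in B6J without B6J#02 (0.12). Nor did Irak3 in MYS without MYS#02 (0.10) or Clec4a1, Wnt8a and Atf3 without MYS#05 (0.069 to 0.20). The count of 3340 genes fell to 2081 without B6J#06, to 1956 without MYS#04 and to 2142 without MYS#05.

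STM2 and MYS differed in the lists of germline genes, 2-cell-like genes and fatty acid synthesis, none of which passed with an estimated correlation (0.483, 0.775 and 0.747). Meiotic and germline genes such as Sycp1, Mael, Dazl and Taf7l rose more in STM2. Genes of the Zscan4 cluster rose in STM2 from near 0 counts. The sphingolipid phosphatase gene Sgpp2 and Irak3 fell in STM2 and rose in MYS, where neither rise passed without MYS#02 (0.070 and 0.10).

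The response of STM2 was higher than that of MYS for 1732 genes and lower for 1638. Ildr1 changed by 1.64 in STM2 and −1.60 in MYS, a difference of 3.24 (SE 0.40, adjusted p = 0.00022). Btn1a1 differed by 3.22 (SE 0.32, 5.4e-05) and the autophagy receptor gene Calcoco2 by 2.57 (SE 0.33, 0.0003), both higher in STM2 alone. Zscan4c (adjusted p = 0.032) went from 0 to 27 counts over the STM2 lines, at least 8.61-fold higher, and Zscan4d (0.0047) from 2 to 85 counts, a ratio of 40.6 with a counting interval of 10.9 to 341. Sgpp2 changed by −2.77 in STM2 and 0.77 in MYS, a difference of −3.54 (SE 0.23, 2.8e-06), although its rise in MYS did not pass without MYS#02 (0.070). Irak3 (−2.35 and 0.98) and Cttnbp2 (−1.43 and 1.84) moved in opposite directions, with differences of −3.32 and −3.27. The rise of Irak3 in MYS did not pass without MYS#02 (0.10) or MYS#04 (0.21). Pnma5 rose by 2.80 in MYS, from 2.95 to 20.4 CPM, a difference of −2.47 (SE 0.17, 3.9e-06). Cyp1a1 rose by 3.63 in MYS and by 1.32 in STM2, a difference of −2.31 (SE 0.53, 0.011), which did not pass without MYS#02 (0.061). Germline genes had 8 higher and 2 lower of 16 (10 higher adjusted over the list alone, 0.00309, adjusted p = 0.483 with an estimated correlation), including Sycp1 (1.92), Taf7l (1.56), Mael (1.43) and Dazl (1.34). The 2-cell-like list had 6 higher and 0 lower of 20 (11 higher adjusted over the list alone, 0.00187, adjusted p = 0.775 with an estimated correlation). With members at 0 counts set to their bound, the median log2 ratio was 2.97 over the 15 members with counts in STM2, 0.24 over 19 in MYS and 1.14 over 20 in B6J. Its response in STM2 and in MYS was not found to differ from that in B6J (0.0580 and 0.0758). Fatty acid synthesis had 6 higher and 1 lower of 19 (8 higher adjusted over the list alone, 0.00115, adjusted p = 0.747 with an estimated correlation), with Mlxipl (1.36), Scd1 (0.93) and Elovl6 (0.90) higher. Histone genes had 5 lower and 0 higher of 48 (3.96e-05, adjusted p = 0.0510 with an estimated correlation), with Hist1h2bk (−1.59) and Hist1h3e (−1.55). Ribosomal protein genes had 23 lower and 4 higher of 96 (42 and 4 adjusted over the list alone, 1.86e-11, adjusted p = 0.483 with an estimated correlation), with Rpl15 (−0.46) lower. Complexes III to V had 11 lower and 0 higher of 37 (18 lower adjusted over the list alone, 3.96e-05, adjusted p = 0.747 with an estimated correlation), with Uqcrq (−0.38, adjusted p = 0.055 without MYS#05), and complexes I and II 8 lower and 0 higher of 41 (0.00134, again 0.747). G2/M and mitosis had 3 lower and 0 higher of 22 (9 lower adjusted over the list alone, 0.000323, adjusted p = 0.747 with an estimated correlation), with Cdca8 (−0.42). Ribosome biogenesis had 3 lower and 0 higher of 26 (7 lower adjusted over the list alone, 0.00111, adjusted p = 0.775 with an estimated correlation), with Rrp12 (−0.45). Of the 12 cold-inducible genes 2 were lower and 0 higher (0.0454, adjusted p = 0.483 with an estimated correlation), Tra2a (−0.45) and Rbm10 (−0.26, not past without MYS#02, MYS#05 or STM2#01, with adjusted p up to 0.059, nor without a filter, 0.056). The count of 3370 genes fell to 2176 without MYS#02, to 1876 without MYS#04, to 2206 without MYS#05 and to 2017 without STM2#01.

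**Figure D5:**
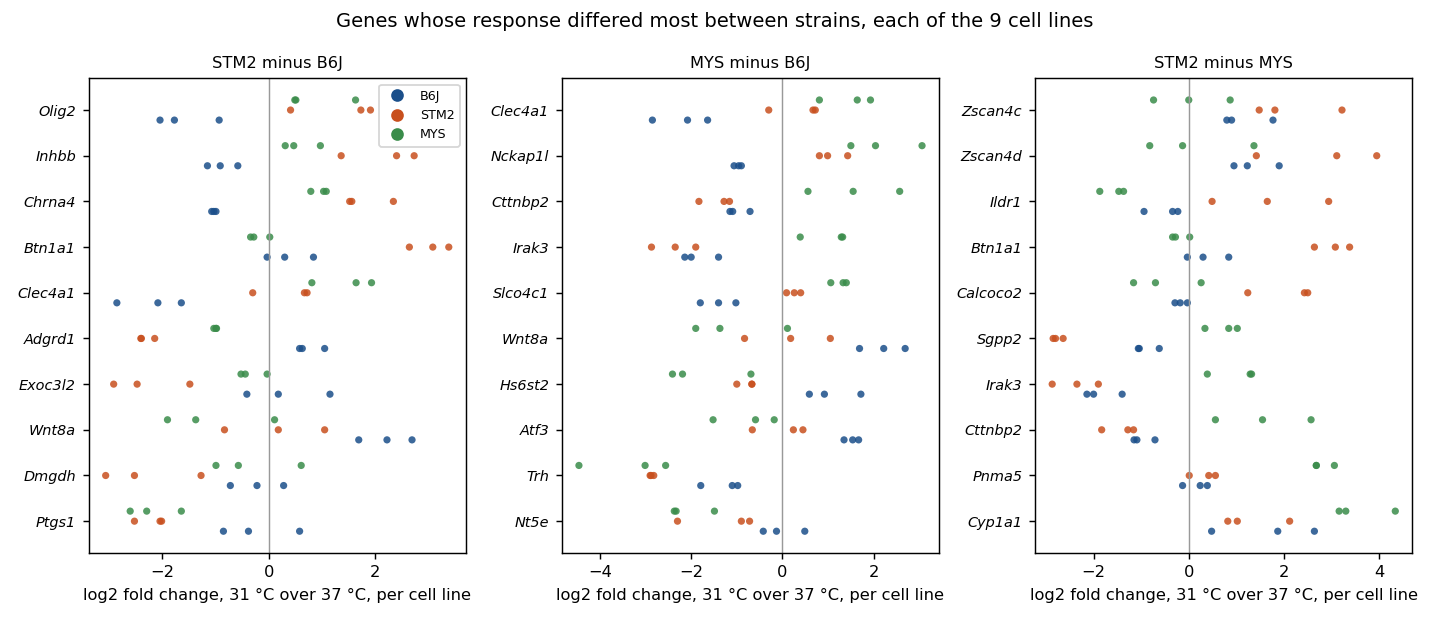
Each dot is the log2 fold change (31 °C over 37 °C) of 1 of the 9 cell lines, coloured by strain, for the genes whose response differed most between each pair of strains. STM2 dots of Zscan4c and Zscan4d rest on 0 and 2 counts at 37 °C and depend on the prior count of 2.

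At 37 °C the strains differed in 14428 of 20241 genes. The non-coding RNA Lncenc1, linked to naive ES cells, was abundant in B6J and nearly absent from STM2 and MYS. Genes of the 2-cell-like state were abundant in B6J, nearly absent from STM2 and lower in MYS. Imprinted genes such as Mest and Impact were higher in STM2 than in B6J. The pyruvate dehydrogenase gene Pdhb and ribosome biogenesis genes were higher in MYS. With an estimated correlation 0 lists passed in the 3 comparisons at 37 °C. Levels at 37 °C are scaled over the 9 libraries at that temperature. All reads were aligned to a genome build of C57BL/6J, so sequence differences of STM2 and MYS and missing copies enter these values.

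Between STM2 and B6J 10653 genes passed, 5418 higher in STM2 and 5235 lower. Lncenc1 was at 274 ± 19.2 CPM (SD, n = 3 lines) in B6J against 0.336 in STM2 and 0.777 in MYS, a log2 difference for STM2 of −9.65 (SE 0.22, edgeR adjusted p = 1.9e-09). Zscan4a had 0 counts in STM2 against 4586 in B6J, at least 1.51e+03-fold lower. Ubd, which encodes a ubiquitin-like protein, had 0 against 4182, at least 1.38e+03-fold lower. BC080695 had 0 against 2740, at least 904-fold lower, and Zscan4d had 2 against 3184, a ratio of 0.000635 with a counting interval of 7.69e-05 to 0.0023. BC080695 has 6 near-identical annotated copies and these Zscan4 genes have 8 each, so counts at or near 0 need not mean absence. Syndig1l differed by 7.60 (SE 0.45, 1.2e-06), at 0.0665 CPM in B6J and 13.3 in STM2, Platr15 by 6.63 and Tespa1 by 6.62. BC002163 (7.22) is annotated as a processed copy of Ndufs5 at 99.4% identity and AK157302 (7.58) matches Isca1 at 99.0%, so their reads are not told apart with certainty. All 19 genes of the 2-cell-like list were lower in STM2 (2.27e-07, adjusted p = 0.959 with an estimated correlation), with a median log2 ratio of −8.53 when members at 0 counts were set to their bound. Imprinted genes had 14 higher and 1 lower of 24 (15 and 2 adjusted over the list alone, 0.0101, adjusted p = 0.959 with an estimated correlation). Mest (2.06) went from 24.3 CPM in B6J to 102 in STM2, and Sgce (2.27), Impact (1.54) and Snrpn (1.19) were higher too. Complexes I and II had 24 higher and 3 lower of 41 (0.00702, again 0.959), with Ndufa11 (0.89) and Ndufb3 (0.84) higher. DNA replication and G1/S had 13 lower and 0 higher of 24 (0.00702, again 0.959), with Tyms (−0.67) and Mcm3 (−0.42).

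Between MYS and B6J 10874 genes passed, 5349 higher in MYS and 5525 lower. Zfp599 had 0 counts in MYS against 4496 in B6J, at least 1.46e+03-fold lower, and was at 24.9 CPM in B6J and 19.7 in STM2. The serotonin receptor gene Htr5a (0 against 3443 counts) was at least 1.12e+03-fold lower and Platr27 (0 against 1912) at least 621-fold lower. Olig2 had 2 counts in MYS against 11750 in B6J, a ratio of 0.000175 with a counting interval of 2.12e-05 to 0.000631. Ubd had 1 against 4182, a ratio of 0.000246 with an interval of 6.21e-06 to 0.00137. Platr15 (8.99), Syndig1l (7.81) and BC002163 (7.28) were higher in MYS, as were Tagap (7.89) and Eno1b (7.02), which have near-identical copies in Tagap1 and Eno1. Eno1b was at 5.92 CPM in B6J, 57.2 in STM2 and 766 in MYS. Rbm3 was lower in both other strains than in B6J, at 245 ± 50.5 CPM in B6J, 125 ± 6.38 in STM2 and 116 ± 7.27 in MYS (adjusted p = 0.00024 and 0.00012), whereas Cirbp was higher in MYS than in B6J (0.72, 0.0011). Nanog was at 1060 CPM in B6J, 678 in STM2 and 541 in MYS (0.0044 and 0.00043), and Pou5f1 and Sox2 did not pass. For MYS, Sox2 did without STM2#02 (0.014), and both Pou5f1 and Sox2 did with every library a sample. Ribosome biogenesis had 18 higher and 1 lower of 26 (20 higher adjusted over the list alone, 0.000336, adjusted p = 0.956 with an estimated correlation), with Bop1 (0.96) and Nop58 (0.68). The tricarboxylic acid cycle had 14 higher and 3 lower of 19 (0.0125, adjusted p = 0.502 with an estimated correlation). Pdhb (1.66) went from 163 CPM in B6J to 513 in MYS, while Pdha1 (−0.90), for the partner subunit, was lower. Complexes I and II had 21 higher and 3 lower of 41 (0.00450, adjusted p = 0.956 with an estimated correlation), including Ndufv1 (0.64), and complexes III to V 20 and 6 of 37 (22 higher adjusted over the list alone, 0.0161, again 0.956), including Cyc1 (0.66). Mitochondrially encoded subunits had 7 higher and 1 lower of 13 (0.0329, again 0.956). Of these mt-Co2 (4.90), mt-Atp6 (4.64), mt-Co3 (4.40) and mt-Nd3 (3.86) have near-identical copies in the reference on chromosome 1. Such copies can share or take reads, so these values need not be differences in level. The share of all counts from mitochondrial DNA at 37 °C, not scaled, was 1.59 to 1.74% in B6J lines and 1.21 to 1.52% in MYS lines. Of 7 cold-shock-domain genes 4 were higher and 0 lower (6 higher adjusted over the list alone, 0.0452, again 0.956), with Lin28b (2.27) highest. The 2-cell-like list had 18 lower and 0 higher of 19 (6.53e-06, again 0.956), with a median of −5.05 with members at 0 counts at their bound. Lysosome and autophagy genes had 16 lower and 1 higher of 28 (17 lower adjusted over the list alone, 0.0169, again 0.956), with Map1lc3b (−1.37) and Ctsa (−0.92).

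Between STM2 and MYS 8909 genes passed, 4591 higher in STM2 and 4318 lower. Zfp599 had 3531 counts in STM2 against 0 in MYS, at least 1.16e+03-fold higher, Pramef17 2773 against 0, at least 910-fold, and Platr27 1788 against 0, at least 587-fold. Pramef17 matches Gm13128 at 99.3% identity, so its 0 counts need not mean absence. AI662270 (8.61, SE 0.45, 8.6e-07) and Xlr3a (9.50, SE 0.78), which has a near copy in Xlr3b, were higher in STM2. Anxa8, which encodes an annexin, was at 37.4 ± 7.65 CPM in MYS and 0.568 in STM2 (−6.04, SE 0.24, 1.5e-07). The ganglioside synthase gene St8sia1 was at 17.8 CPM in MYS and 0.251 in STM2 (−6.14), and Mir703 (−6.78), which matches Eef1a1 at 98.2% identity, was lower in STM2. BC080695 (0 against 102 counts) was at least 34.5-fold lower and Zscan4a (0 against 26) at least 8.80-fold lower in STM2, and both have several near-identical copies. Imprinted genes had 12 higher and 2 lower of 24 in STM2 (13 and 4 adjusted over the list alone, 0.0224, adjusted p = 0.975 with an estimated correlation), including Plagl1 (2.49) and Snrpn (1.27). The unfolded protein response had 8 higher and 0 lower of 18 (10 higher adjusted over the list alone, 0.0490, again 0.975), including Edem1 (0.76). DNA replication and G1/S had 16 lower and 0 higher of 24 (0.00141, again 0.975), including Rrm2 (−1.04). Ribosome biogenesis had 13 lower and 1 higher of 26 (2 higher adjusted over the list alone, 0.0122, again 0.975), including Wdr12 (−0.56). The proteasome had 13 lower and 0 higher of 31 (0.0115, again 0.975), including Psmd14 (−0.56).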

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

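The tests of X-linked dosage, of Xist, of unspliced RNA, of summed gene copies, of a strain variant and of abundant B6J-specific genes were chosen after the result was seen. The values below stand out because the response to 31 °C differed between strains, as tested by the interaction of strain and temperature. The response differed among the 3 strains for 6288 genes, with 4152 between STM2 and B6J, 3340 between MYS and B6J and 3370 between STM2 and MYS. Over 40 of the 280 regroupings of the 9 lines, 1, the real one, gave as many as 6288 genes and the highest other gave 696. This argues against chance as its source but does not exclude it, since not all regroupings were drawn. For the common response 1 of 40 drawn from 256 gave as many as 14550, against 3397 for the highest other, and for any strain difference at 37 °C 1 of 40 from 280 gave as many as 14428, against 4729. For both, chance is argued against but not excluded.

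Regroupings are too few for a share under 0.05 in the other comparisons, where only 1, the real one, gave as many genes. The pairwise responses have 10 each, with highest others of 1 gene for STM2 and B6J, 0 for MYS and B6J, and 1 for STM2 and MYS. The responses within B6J (10870), STM2 (11839) and MYS (10676) have 4 each, with a highest other of 0. The pairs at 37 °C have 10 each, at 10653 for STM2 and B6J, 10874 for MYS and B6J and 8909 for STM2 and MYS, all with a highest other of 0. Each single line also has 10, with 0 for the highest other, beside 11090 genes in B6J#02, 10225 in B6J#03, 10615 in B6J#06, 10905 in MYS#02, 9907 in MYS#04, 9942 in MYS#05, 11218 in STM2#01, 11318 in STM2#02 and 8843 in STM2#03.

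The response of STM2 minus that of B6J was higher for Olig2 (3.20), Inhbb (3.02), Chrna4 (2.86), Btn1a1 (2.69) and Clec4a1 (2.57). It was lower for Adgrd1 (−3.10), Exoc3l2 (−2.52), Wnt8a (−2.19), Dmgdh (−2.03) and Ptgs1 (−2.03). Lists given here and in the following paragraphs on pairs of strains passed with the preset correlation, and 0 passed with an estimated one. Among gene lists, the median difference was 0.29 for naive and 0.20 for general pluripotency, 0.19 for the unfolded protein response and 0.19 for G1/S genes. It was −0.81 for ATF4 targets, −0.55 for histones, −0.15 for ribosomal proteins, −0.14 for complexes I and II, −0.13 for complexes III to V and −0.12 for ribosome biogenesis.

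Between MYS and B6J the response was higher in MYS for Clec4a1 (3.75), Nckap1l (3.21), Cttnbp2 (2.83), Irak3 (2.82) and Slco4c1 (2.71). It was lower for Wnt8a (−3.52), Hs6st2 (−3.02), Atf3 (−2.22), Trh (−2.13) and Nt5e (−2.05). List medians were 0.33 for naive and 0.27 for general pluripotency, 0.20 for G1/S genes, −0.45 for ATF4 targets and −0.10 for NRF2 targets.

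Between STM2 and MYS the response was higher in STM2 for Ildr1 (3.24), Btn1a1 (3.22) and Calcoco2 (2.57), and for Zscan4d (adjusted p = 0.0047) and Zscan4c (0.032). Genes with a lower response were Sgpp2 (−3.54), Irak3 (−3.32), Cttnbp2 (−3.27), Pnma5 (−2.47) and Cyp1a1 (−2.31). The 2-cell-like list passed with the preset correlation (camera adjusted p = 0.00187) and not with an estimated one (0.775). Medians were 0.74 for germline genes, 0.28 for fatty acid synthesis, −0.93 for histones, −0.18 for G2/M genes, −0.17 for complexes III to V, −0.15 for ribosomal proteins, −0.10 for complexes I and II, −0.10 for ribosome biogenesis and −0.09 for cold-inducible genes.

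Genes under 1 CPM rose at 31 °C by a median of 0.38. Depth is argued against, because 9 of 9 lines had more genes detected at 31 °C after thinning to 15836662 counts. A uniform background such as genomic DNA is argued against by silent receptor genes, which gained at most 0.01 of what sense-intronic genes gained. The 555 genes at 300 CPM or more left a log2 rise of at most 0.06 in the unscaled count share outside them. This argues against a smaller share of these genes as the source. Genes from 10 to 100 CPM fell too, and a broader shift of composition was not tested. More unspliced RNA stays open, because the median of sense-intronic, antisense and bidirectional-promoter genes exceeded that of 9.3% of matched lists of coding genes, which rose alike and can hold unspliced RNA too. The culture temperature itself stays open, and other technical sources were not tested.

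Lines B6J#06 and MYS#04 had 16 and 3 counts of 4 Y-linked genes over 6 libraries each, against 168 to 384 CPM in the libraries of the other lines. A pair of active X chromosomes is argued against by X-linked genes, which differed by 0.02 from the other lines of the strain. An inactivated X chromosome is argued against by Xist, at most 2.69 CPM in the 12 libraries, and a wrong strain by 12 of 12 libraries correlating best with a line of their own strain. A single X chromosome, by loss of the Y chromosome or otherwise, stays open and was not tested.

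Genes of the 2-cell-like state rose in STM2 from near 0 counts. Reads moving between near-identical copies are argued against by the sum over all copies, which rose by at least 1.90 in each STM2 line. A strain variant that lowers counts alike at both temperatures would give no rise. The value set against it, at least 2.14, is the rise of the list itself, so it tests nothing further. RNA of B6J cells stays open. In the test written beforehand, the list needs 0.535 to 0.907 of the B6J share that 34 other B6J-specific genes show. This result went with carry-over but cannot decide the question. All reads of the 34 genes were counted as B6J share, so a rise of these genes in STM2 cells themselves would give it too. A second test, made after that result was seen, gave an upper limit for Lncenc1 of at most 0.593 of the needed share in each STM2 line, but the limits of the other 3 of its 4 abundant genes exceeded the needed share in at least 1 line. A difference between the strains stays open too, as untested, and the rise cannot be told apart from carry-over of B6J RNA with these data.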

How the results depend on the processing

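The settings without scaling factors, with protein-coding genes alone and without the 2 lines that nearly lack Y-linked reads were added after the data were seen. Where a value moved, the cause was not tested. Of 19152 values for 286 gene results, 18999 kept direction and side of the threshold, 128 no longer passed, 19 newly passed and 6 reversed. Many of these values come from leaving out 1 of the 54 libraries, where only 1 value changed. Without the cell line block, which gives at most 1 value per gene result, 77 values no longer passed. With a cell line left out 29 no longer passed and 5 reversed. The reversed values are Ddx3y in the common response without scaling factors (0.12) and without B6J#02 (0.01), Xist without MYS#02 (−0.08) and without STM2#01 (−0.03), Pou5f1 in MYS minus B6J at 37 °C without MYS#05 (−0.13) and Wnt8a in STM2 without STM2#02 (−0.31). Without scaling factors the median of all genes moved from 0.03 to 0.18. Counts of genes moved by at most 1.5 times with RLE size factors, DESeq2, no filter, autosomal or protein-coding genes alone, a spread shared over all 54 libraries or any single library left out. Depth limits what can be said of genes near 0 counts.

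Without the cell line block, genes past the threshold were 6090 in B6J, 7359 in STM2, 6283 in MYS, 536 for any difference in response, 383 for STM2 and B6J, 216 for MYS and B6J and 205 for STM2 and MYS. With every library a sample there were more, at 12909 for any difference, 9499, 8880 and 9178 for the same 3 pairs, and 16163 for STM2 and B6J and 15064 for STM2 and MYS at 37 °C. Replicate numbers do not pair the samples, with correlations of −0.03 to 0.08 between equal numbers, and a replicate block gave 12784, 9414, 8714 and 9115. Without the 2 lines that nearly lack Y-linked reads there were fewer, at 3211, 2516, 1045 and 1555.

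Leaving out a cell line gave 2753 to 4549 genes for STM2 and B6J, 1956 to 3985 for MYS and B6J and 1876 to 3453 for STM2 and MYS. Over the same omissions Xist in the common response ran from −0.08 to 0.20, Ddx3y from −0.06 to 0.01, and Pou5f1 in MYS minus B6J at 37 °C from −0.13 to 0.27. Wnt8a in STM2 ran from −0.31 to 0.63.

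Gene lists depended on the test. With an estimated correlation 0 of 273 list results passed, 0 in each comparison, against 60 with the preset one. With fry 32 passed in the common response, 6 for STM2 and B6J, 0 for MYS and B6J and 5 for STM2 and MYS, and at 37 °C 16, 16 and 8 for the same pairs.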

Other observations

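Processed pseudogenes had a median change of −0.16 at 31 °C, with 211 higher and 634 lower of 2278, while antisense genes had 0.45, with 407 higher and 66 lower of 1024. Coding genes of like abundance rose as well. Sense-intronic, antisense and bidirectional-promoter genes together had a median of 0.48, against 0.53 for lists of coding genes matched for abundance. These values enter no comparison between strains. Counting with a known strand setting would separate antisense transcripts from reads of overlapping genes.

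The 34 B6J-specific genes outside the 2-cell-like list reached 0.701, 2.03 and 0.535% of their B6J level in STM2#01, STM2#02 and STM2#03 at 31 °C. Reads that carry B6J or STM2 sequence variants would tell B6J RNA from transcripts of STM2 cells, and sequence reads were not used here.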
